A study of Mus musculus and Homo sapiens and Macaca mulatta with 14 samples.

How the data were processed

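Poly(A) RNA of 14 libraries was measured by RNA sequencing, and the deposited values came in 3 tables, one for the mouse cultures, one for mouse epiblast tissue and one for the primate cultures. Per the file headers, the authors deposited FPKM values (fragments or reads per kilobase of transcript and library size) for each library. The labels name CASAVA 1.8.2, STAR 2.2.0c and HOMER as tools without giving their order or settings, and list mm9, hg19 and, for the primate libraries, GRCh37 as builds. The total used as library size and any filter by the authors are not stated. The libraries were made with a strand-specific kit per the labels' protocols, but the strand used in counting is not given. The tables held 31641 transcript entries for 23952 gene symbols (mouse cultures), 24016 for 24016 (epiblast) and 25572 for 25571 (primates). The rhesus and chimpanzee values stand on human RefSeq transcripts, so reads that did not match the human sequence are missing from them. Coordinates are given as the tables hold them.

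Library columns were matched to the labels by name. The mouse columns named IS-EPIs were taken as the rsEpiSC libraries, because the cell type label of those samples carries that name. Primate columns with the prefix LP were taken as the rs cultures, because the rhesus and chimpanzee columns carry it. Per the labels, EpiSC and rsEpiSC were both derived from E5.75 embryos and grown on mouse embryonic fibroblasts (MEFs) for 20 to 25 passages. EpiSC medium held FGF2 at 12 ng/ml, activin A at 20 ng/ml and 20% KSR. rsEpiSC medium held IWR1 at 2.5 uM and 20 ng/ml of a factor that the label leaves out. Human, rhesus and chimpanzee rs media held FGF2 at 20 ng/ml and IWR1 at 2.5 uM. IWR1 stabilises Axin and so inhibits canonical Wnt signalling. The rsEpiSC medium as stated has neither activin A nor KSR, so the mouse groups differ in several components at once.

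The tables give no read counts. FPKM times transcript length fell on whole multiples of 1 step per library (within 0.1 of a step for 100% of the low values looked at), and the inverse of that step was taken as the implied depth, in mega reads (M reads). It is not a total that the files state, so no counting interval is built on it. It came to 49.7, 56.8, 56.4 and 50.5 M reads for EpiSC replicates 1 and 2 and rsEpiSC replicates 1 and 2. For the anterior-proximal, anterior-distal, posterior-proximal and posterior-distal epiblast it was 11.6, 23.3, 15.5 and 24.4 M reads. For H1 ESC, H9 ESC, H1 rsESC and H9 rsESC it was 20.7, 16.0, 55.4 and 16.6 M reads, for rhesus 9.78 M reads and for chimpanzee 13.5 M reads. For the mouse cultures, 64.4% to 65.2% of those multiples were even, against 39.3% to 43.5% in the other tables, so mates of a pair may have been counted singly there. The step equals 0.0176 to 0.0201 FPKM per kilobase in the mouse cultures and reaches 0.102 in the rhesus library.

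Analyses were run in R 4.3.3 with limma 3.58.1. For each gene symbol the transcript with the highest mean over the libraries compared was used, genes with a mean of at least 1 FPKM were kept, and log2(FPKM + 1) was analysed, so all log2 fold changes are on that scale. Linear models (limma lmFit, eBayes with a trend of variance on expression) were tested on both sides with Benjamini-Hochberg adjustment over all genes kept. A gene was called higher or lower at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The mouse model held the group alone. The human model held the group and the cell line, since the labels pair the lines H1 and H9. All p-values measure the spread between these libraries only, since the labels do not say that libraries of 1 group came from separate cultures. Replicates were checked for copies of the same library and kept apart. On the implied reads, taken as pairs in the mouse cultures, their chi-square per gene was 168 in EpiSC, 25.2 in rsEpiSC, 16.1 in ESC and 2.59 in rsESC. These values are rough and serve that check alone. Across genes, deviations of the libraries that share a replicate number correlated at -0.20 in mouse and 0.0073 in human.

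26 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were tested with limma camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists tested (24 in mouse, 22 in human). Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera tests on the residual degrees of freedom of the fit (2 in mouse, 1 in human). A list can fail there for that reason alone, whatever its correlation. Lists with fewer than 5 members kept were not tested: visceral endoderm (2 members kept in mouse, 4 in human) and Hox genes (0 in both) in either species, and in human primitive streak and mesendoderm (4) and definitive endoderm (3). Named genes are the 10 with the largest change in each direction among called genes, up to 4 called members per list (or 3 where none was called) with the largest change, and a fixed few: Pou5f1, Sox2, Nanog and, in mouse, T, Fgf5, Otx2 and Axin2. A few genes that the rule names are not reported here. Unnamed transcripts, microRNAs and small nucleolar RNAs were passed over. Other genes are said to have been chosen after their values were seen.

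The 4 epiblast regions had 1 library each, so the planned comparison used no test. A limma model with both contrasts as additive terms (1 residual degree of freedom per gene, same thresholds) was added after the values were seen. A gene counted as different when log2(FPKM + 1) differed by at least 1 in the same direction in both pairs of a contrast. A list's median was placed among 10000 random lists matched on mean expression in 20 bins. The same placing was used to compare culture changes with regions and mouse changes with human changes, where mouse and human genes were joined by symbol. For rhesus and chimpanzee, the share of human called genes whose level lay nearer the human rsESC mean than the ESC mean is given with an exact (Clopper-Pearson) 95% interval.

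From the primate table, 118 entries (chromosome Y genes and X-inactivation RNAs) were left out of every step except 1 alternative, a choice made after the table was seen. The cell line labels were checked on autosomal genes outside chromosome 1 from 140 Mb. There 1 of the 2 rsESC libraries lay nearer the ESC library of the other line label. The check takes the ESC labels as right and cannot tell a wrong label from another difference between the ESC libraries. Values without the line in the model are therefore given too. In a check for mixed-up samples, chosen after the values were seen, 1 of the 4 mouse culture libraries did not match the other 3. Alternatives covered the pseudocount (0.1 or 5), the filter on low values, the scaling, the entry used per symbol, the variance trend, the block and each library left out. For human, leaving out a library used the model without the cell line, because no residual degrees of freedom remain with it. A group left with 1 library is then assumed to vary like the other group. The alternatives that leave out chromosome regions, that keep the 118 entries, that leave out genes differing between the ESC libraries, that drop the line from the model in the cross-species comparisons, or that fit the epiblast additively were chosen after seeing the data.

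The models were tested on simulated data with 200 changed genes. With moderated gene SDs, the mouse model (11880 genes) recovered 71% of genes changed by 1.5 and 99% of those changed by 3 on the log2 scale with 7 false calls, and the human model (13214 genes) recovered 100% of both sizes with 4 false calls. Moderated SDs are shrunk towards the fitted trend and scatter less than the true ones, so these shares may be too high. A first simulation drew from the raw residual SDs, which rest on few degrees of freedom and so scatter more than the true ones. There the mouse model recovered 28% and 69% with 1 false call and the human model recovered 0% of either size, with 0 false calls.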

Results

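RNA sequencing of poly(A) RNA was deposited for mouse, human, rhesus macaque and chimpanzee pluripotent cultures and for mouse epiblast tissue, 14 libraries in all. The mouse cultures were epiblast stem cells (EpiSC, 2 libraries) and cells named rsEpiSC (2 libraries), which the title of the series places among studies of an alternative pluripotent state. The epiblast of E6.5 embryos was divided into anterior-proximal, anterior-distal, posterior-proximal and posterior-distal regions with 1 library each. The human cultures were conventional embryonic stem cells (ESC) and rsESC, each from the lines H1 and H9 (2 libraries per group). A rhesus rsESC library and a chimpanzee rsiPSC library (induced pluripotent cells) completed the set. The files give no read totals. The spacing of the values implied 49.7 to 56.8 M reads (mega reads) in the mouse cultures, 11.6 to 24.4 M reads in the epiblast and 9.78 to 55.4 M reads in the primates.

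Libraries of the same group differed most in the EpiSC group, where the SD of the log2 difference between both libraries was 0.65. It was 0.28 in rsEpiSC, 0.33 in human ESC and 0.15 in human rsESC. All fold changes are on the log2(FPKM + 1) scale, and values are FPKM given as mean ± SD (n = 2 libraries per group) unless stated otherwise.

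The first comparison asked how mouse rsEpiSC differ from EpiSC, both pluripotent by name. The libraries labelled rsEpiSC held little of the pluripotency factor Pou5f1, which fell from 888 ± 141 to 10.9 ± 3.25 FPKM (NM_013633, mm9 chromosome 17, 35642977 to 35647722; log2 fold change -6.24, SE 0.26, adjusted p = 0.00438). Nanog, another core factor, fell from 54.5 ± 11 to 1.73 ± 1.16, and the epithelial adhesion gene Cdh1 (E-cadherin) fell from 184 ± 15 to 0.795 ± 0.437. Sox2, a factor of both pluripotent and neural cells, rose from 8.05 ± 0.304 to 122 ± 7.38 (log2 fold change 3.76). Wnt1, a signal of the midbrain-hindbrain boundary, rose from 0.0075 ± 0.0106 to 50.4 ± 0.887, and the neural transcription factors En1, Rax and Pax6 rose to 14.9 ± 2.76, 21.4 ± 12.0 and 16.7 ± 5.76 FPKM.

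Of 11880 genes tested with limma, 1819 changed, 794 higher and 1025 lower in rsEpiSC, and 609 of these changed at least 4-fold. Besides Wnt1, the named genes with the largest rise were the non-coding RNA Rian (5.11), the growth factor Ptn (5.06), Rps18 (4.88), the forebrain factor Fezf2 (4.73), Mid1 (4.70), the Wnt antagonist Frzb (4.62), the cerebellin Cbln1 (4.51), the BMP target Id3 (4.42) and Rpl3 (4.35), all as log2 fold changes. Rps18 and Rpl3 are ribosomal protein genes, whose rise may not be one of expression (see that list below). The largest falls were in the tight junction genes Cldn6 (-7.30) and Cldn4 (-6.81), Cdh1 (-6.71), the Nodal co-receptor Tdgf1 (-6.38), Tinagl1 (-6.31), Pou5f1, S100a10 (-5.83), Chchd10 (-5.58) and Atp1b1 (-5.57). Hspb1, a small heat shock protein gene, was listed at 0 in both rsEpiSC libraries and stood at 56.5 ± 6.00 FPKM in EpiSC. The 2 groups did not overlap for 7980 genes (67.2%, where chance gives 33.3%).

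**Figure D1:**
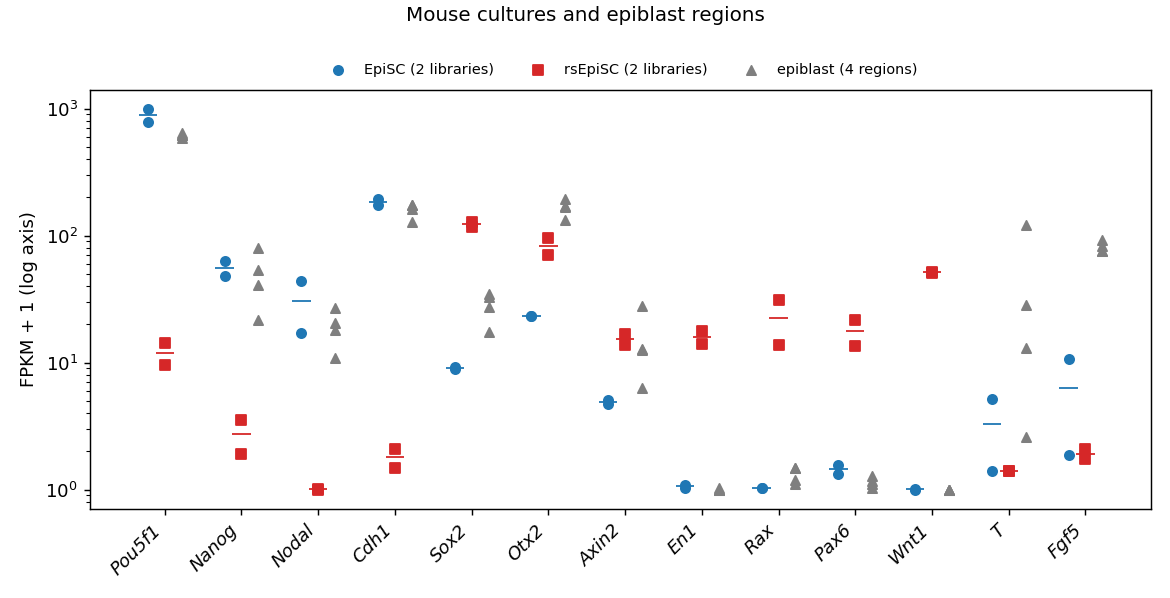
FPKM + 1 (log axis) of named genes in EpiSC (circles) and rsEpiSC (squares), 2 libraries each with the mean as a line, and in the 4 epiblast regions (triangles, 1 library each). Pou5f1 lies at 888 FPKM on average in EpiSC and at 10.9 in rsEpiSC, while Sox2 lies at 8.05 and 122.

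The epithelial list fell as a whole. All 18 of its tested members were called lower, over all genes and adjusted over the list alone, among them Cldn6, Cldn4, Cdh1 and the protease St14 (84.9 ± 24 to 0.976 ± 0.176). Its camera adjusted p was 1.2e-15, and adjusted p = 0.358 with an estimated correlation. The mesenchymal list did not pass (adjusted p = 0.866), with 4 of 17 members higher and 2 lower (5 and 4 adjusted over the list alone). Its N-cadherin gene Cdh2 rose from 3.39 ± 2.48 to 46.6 ± 4.57 and the repressor Zeb1 rose from 2.14 ± 0.0509 to 15 ± 0.455, while Tagln and Sparc fell by 2.71 and 1.78 on the log2 scale.

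Among neuroectoderm genes, 10 of 14 rose and 0 fell (10 and 0 adjusted over the list alone), with the largest changes in Rax (4.34), En1 (3.89), Lhx5 (3.58) and Pax6 (3.58). The list's adjusted p was 7.3e-06, and 0.358 with an estimated correlation. The anterior and neural factor Otx2 rose from 22.3 ± 0.150 to 82.2 ± 18.9.

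Nodal and Activin targets fell, with 9 of 12 members lower and 0 higher (10 and 1 adjusted over the list alone), adjusted p = 7.3e-06 and 0.358 with an estimated correlation. Tdgf1 dropped from 124 ± 131 to 0.0105 ± 0.0148, Lefty1 from 59.2 ± 48.1 to 0.124 ± 0.0184, and Nodal from 29.7 ± 19.1 to 0.0085 ± 0.012. Activin A is a component of the EpiSC medium and not of the rsEpiSC medium as the labels give it. Canonical Wnt targets did not pass as a list (adjusted p = 0.0917, 0.0339 to 0.562 over the alternatives other than the estimated correlation, with a pass, higher, only without rsEpiSC replicate 2), although 5 of 14 members rose and 0 fell (5 and 0 adjusted over the list alone). These included Lef1 (3.01), Apcdd1 (1.93), Sp8 (1.81) and Axin2, a general Wnt target, which rose from 3.88 ± 0.277 to 14.3 ± 2.18 in the culture that held the Wnt inhibitor IWR1. BMP targets were called in both directions (3 of 9 higher, 2 lower, the same numbers adjusted over the list alone, list adjusted p = 0.597), with Id3, Id1 (2.93) and Id2 (1.99) higher and Gata3 (-1.93) lower. FGF and ERK targets did not pass either (adjusted p = 0.705), with 2 of 18 higher (Dusp4 1.95, Spry1 1.40) and 3 lower, among them Ier3 (-2.30) and Etv4 (-1.88), and the same numbers adjusted over the list alone.

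The pluripotency lists were mixed. Core pluripotency genes were not called as a list (adjusted p = 0.189), with 3 of 15 higher and 5 lower (3 and 7 adjusted over the list alone), and Utf1 fell with Pou5f1, Nanog and Tdgf1 (170 ± 78.6 to 3.57 ± 1.79). Whether the core list passes depends on the fit and on single libraries: it was called lower with a replicate block (adjusted p = 0.0380), without EpiSC replicate 1 (0.0284) and without rsEpiSC replicate 1 (0.0187) or 2 (0.0168), in a range up to 0.457 over the alternatives other than the estimated correlation. Naive pluripotency genes fell, 4 of 8 members lower and 0 higher (5 and 0 adjusted over the list alone), including Nr5a2 (-3.56), Fgf4 (-2.68), Klf5 (-2.44) and Fbxo15 (-2.11). That list's adjusted p was 0.00123, and 0.411 with an estimated correlation. Genes of the post-implantation epiblast and primed state went both ways (4 of 19 higher, 4 lower, the same adjusted over the list alone, list adjusted p = 0.709), with Cdh2 (3.56) higher and Cldn6, Nodal (-4.77) and the receptor gene Epha1 (-3.42) lower. The primed marker Fgf5 was at 5.31 ± 6.26 in EpiSC and 0.914 ± 0.221 in rsEpiSC (adjusted p = 0.354), and did not pass. The streak factor T was at 2.29 ± 2.67 and 0.406 ± 0.00566 (adjusted p = 0.360), and did not pass either.

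Of germ layer and germ cell lists, definitive endoderm was called lower (3 of 6 members lower, 1 higher, or 4 and 1 adjusted over the list alone, list adjusted p = 0.0454). With an estimated correlation that adjusted p was 0.615, without EpiSC replicate 1 it was 0.0966, without EpiSC replicate 2 it was 0.112 and with a pseudocount of 0.1 it was 0.0540, in a range from 0.00995 over the alternatives other than that correlation. Its called members were the keratins Krt18 (-3.77) and Krt8 (-3.26), which the epithelial list also holds, Foxa3 (-1.17) and, upward, the chemokine receptor Cxcr4 (3.31). Primitive streak and mesendoderm genes did not pass (adjusted p = 0.705; 2 of 7 higher, 2 lower, or 2 and 3 adjusted over the list alone), with Wnt5b (2.12) and Pdgfra (1.93) higher and Wnt3 (-2.16) and Fgf17 (-1.60) lower. Extraembryonic ectoderm and trophoblast genes did not pass (adjusted p = 0.705; 2 of 8 higher, 3 lower, or 2 and 4 adjusted over the list alone), with Sox21 (3.48) higher and Gata3 and Tfap2c (-1.85) lower. Primordial germ cell genes did not pass (adjusted p = 0.709; 2 of 5 in each direction, the same adjusted over the list alone), with Kit (2.57) and Elavl2 (1.94) higher and Ifitm3 (-4.18) lower.

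Cholesterol biosynthesis genes rose together, 10 of 24 members higher and 0 lower (15 and 0 adjusted over the list alone), adjusted p = 4.7e-08 and 0.670 with an estimated correlation. Lss, which encodes lanosterol synthase, rose from 16.0 ± 0.856 to 85.8 ± 19.7, and Stard4 (2.00) and Fdps (1.74) rose with it. ATF4 and amino acid stress genes fell (5 of 22 lower, 0 higher, or 9 and 0 adjusted over the list alone, list adjusted p = 9.2e-05, and 0.674 with an estimated correlation), among them Trib3 (-4.04), Slc7a3 (-2.40), Atf4 (-1.73) and Slc7a5 (-1.47). The list of p53 targets fell with the same adjusted p values (7 of 19 lower, 1 higher, or 9 and 1 adjusted over the list alone), including Perp (-3.43), Plk2 (-2.96), Phlda3 (-2.41) and Mdm2 (-2.32). Oxidative phosphorylation genes were lower as a list while 0 of 37 members were called (0 adjusted over the list alone), with adjusted p = 0.000125 and 0.615 with an estimated correlation, a median log2 fold change of -0.37, and Ndufb5 (-0.68), Atp5e (-0.65) and Uqcrq (-0.61) as the widest differences. In limma, 4300 genes of all had an unadjusted p under 0.05.

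Cell cycle genes were higher as a list (adjusted p = 0.000218, median 0.61, and 0.764 with an estimated correlation), although its 2 called members of 35, the inhibitors Cdkn2a (-2.57) and Cdkn1a (-1.53), were lower (1 adjusted over the list alone). Glycolysis genes did not pass (adjusted p = 0.0826; 3 of 24 higher, 2 adjusted over the list alone), with Aldoc (2.06), Pfkfb4 (1.17) and Gapdh (1.05) higher. The glycolysis list was called higher with a replicate block (adjusted p = 0.0321) and without rsEpiSC replicate 2 (8.8e-05), in a range up to 0.214 over the alternatives other than the estimated correlation. DNA methylation and demethylation enzymes did not pass (adjusted p = 0.705; 3 of 14 higher, 1 lower, or 3 and 2 adjusted over the list alone), with Uhrf1 (1.58), Dnmt1 (1.44) and Tet3 (1.40) higher and Apobec1 (-2.71) lower. Markers of the fibroblast feeder layer did not pass (adjusted p = 0.705; 1 of 14 in each direction, the same adjusted over the list alone), with Fbln2 (1.86) higher and the collagen gene Col1a1 lower (40.5 ± 29.8 to 1.47 ± 0.487). Ribosomal protein genes did not pass (adjusted p = 0.189), with 4 of 76 higher, the same adjusted over the list alone, and 72 not called. Those 4 were Rps18, Rpl3, Rpl21 (4.08) and Rpl26 (3.99), a gene family with many near-identical copies in the genome. Rps18 was at 333 and 394 FPKM in rsEpiSC, 14.9 and 8.53 in EpiSC and 11.2 to 11.3 in the epiblast regions. Whether reads of such copies were assigned alike in all libraries was not tested, so these 4 rises may not be changes in expression. Over the alternatives other than the estimated correlation that list's adjusted p ranged from 0.00255, a call lower without EpiSC replicate 2, to 0.985. Replication-dependent histones, which mostly lack poly(A) tails, did not pass (adjusted p = 0.713; 0 of 6 called, 0 adjusted over the list alone), with Hist1h4i at 1.54, Hist1h1c at -1.19 and Hist3h2ba at 0.84. Visceral endoderm genes (2 members kept) and Hox genes (0 kept) were not tested.

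**Figure D2:**
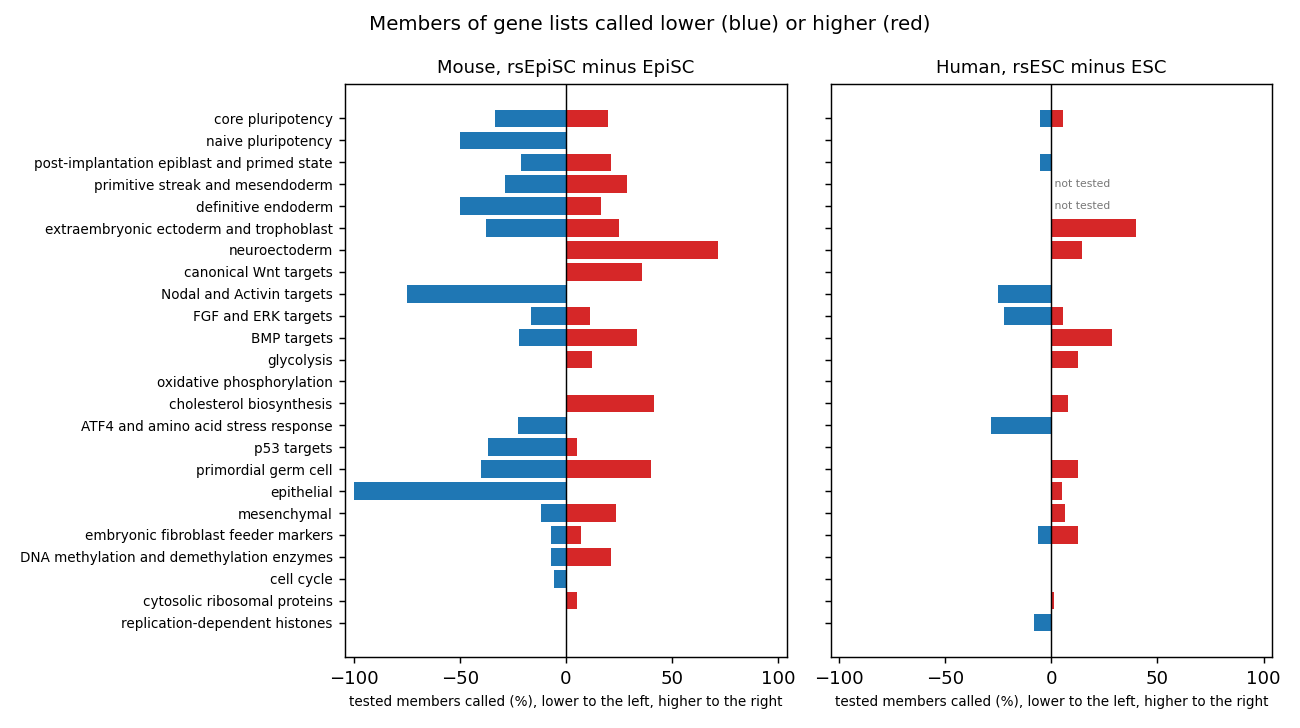
Percent of the tested members of each gene list called higher (red, to the right) or lower (blue, to the left) in mouse rsEpiSC against EpiSC and in human rsESC against ESC. In mouse 18 of 18 epithelial members were lower and 10 of 14 neuroectoderm members higher, and in human 6 of 21 ATF4 members were lower.

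Genes of chromosome 12 moved with the groups: the median log2 fold change of its 427 genes was -0.35, and from 70 Mb onward it was -0.61 over 276 genes (mm9). Rian lies there but rose, and Sp8 and Id2 are also on chromosome 12. Leaving chromosome 12 out gave 1694 changed genes. The number of calls rests on how the spread is estimated. With 1 rsEpiSC library left out it came from the EpiSC pair alone (SD of the log2 difference 0.65, against 0.28 in rsEpiSC). Of the main calls tested, 0 of 1779 changed sign without rsEpiSC replicate 1, 0 of 1773 without replicate 2 and 1 of 1767 without EpiSC replicate 2. These genes were called with all libraries in, so a kept sign with 1 library left out was nearly fixed in advance. The numbers called in such fits are given below with the processing. The number of calls was 952 with a pseudocount of 5, 341 without a filter on low values and 1149 with a mean of at least 5 FPKM.

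The second question was how regions of the E6.5 epiblast differ. Genes of the primitive streak, where gastrulation starts, were higher posteriorly and proximally as a list (median log2 difference 1.53 and 1.87). T and Mixl1 were highest in the posterior-proximal region, and the anterior-proximal region stood above the posterior-distal one. T (Brachyury) stood at 121 FPKM in the posterior-proximal region, 27.7 in the anterior-proximal, 12.0 in the posterior-distal and 1.61 in the anterior-distal region. Mixl1 followed the same order of regions with 195, 37.5, 30.0 and 3.49 FPKM. Id1, a direct BMP target, was instead proximal on both sides, at 47.5 (anterior) and 48.1 (posterior) against 2.60 and 1.46 in the distal regions. With 1 library per region there is no spread between replicates, and the counts below rest on pairs of regions. A limma model with both contrasts as additive terms, added after the values were seen, leaves 1 residual degree of freedom per gene and takes any interaction of the contrasts as error. In it T had an adjusted p of 0.00525 posteriorly and 0.000965 proximally, Mixl1 0.00525 and 0.00345, and Id1 0.456 and 0.00290.

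Of 11059 genes, 49 differed at least 2-fold in the same direction in both posterior-anterior pairs, 42 of them higher posteriorly. Of the proximal-distal contrast, 51 did, 48 of them higher proximally, and 21 genes were higher in both. The additive model called 32 genes posteriorly (29 higher, 3 lower), 31 of them among the 49, and 34 proximally (34 higher, 0 lower), 27 of them among the 51. The widest posterior differences were in Lhx1 (mean log2 difference 2.92), Mixl1 (2.57), Foxa2 (2.33), the retinoic acid degrading enzyme Cyp26a1 (2.2), T (2.2), Frzb (2.07), Sp5 (2.02), Adamts9 (2.01), Cer1 (1.96) and Aplnr (1.93). The widest proximal differences were in Mesp1 (4.45), Id1 (4.04), T (3.34), Evx1 (3.21), Mixl1 (2.88), Cyp26a1 (2.66), Snai1 (2.57), Frzb (2.47), Sp5 (2.34) and Wnt3 (2.14). In the additive model all of these passed except Frzb (adjusted p = 0.0514), Cer1 (0.215) and Aplnr (0.166) posteriorly. Genes that were lower, 7 posteriorly and 3 proximally, were all microRNA or small nucleolar RNA genes, which the naming rule passes over.

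**Figure D3:**
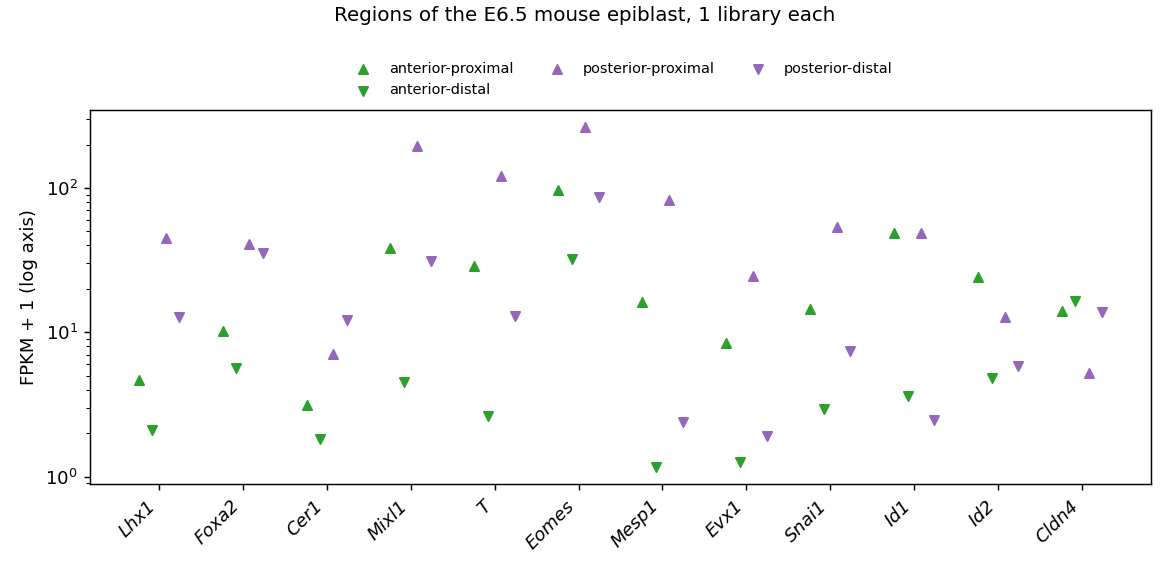
FPKM + 1 (log axis) of named genes in the 4 epiblast regions, 1 library each, with anterior in green, posterior in purple, proximal as upright and distal as inverted triangles. Mesp1 reaches 81.0 FPKM in the posterior-proximal region against 1.38 in the posterior-distal one.

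Primitive streak and mesendoderm genes were higher posteriorly in 12 of 18 members (median 1.53) and proximally in 11 of 18 (median 1.87), each above all random lists of equal size (percentile 100). Definitive endoderm genes were higher posteriorly in 5 of 11 members (median 1.47), among them Foxa2, Cer1, Gsc (1.90) and Gata6 (1.88), and proximally in 1, Gata4 (1.97). Foxa2 stood at 39.8 FPKM in the posterior-proximal and 34.6 in the posterior-distal region, and Cer1 at 6.12 and 11.1. Canonical Wnt targets were higher in 3 of 15 members posteriorly and 6 of 15 proximally, including Sp5, Tnfrsf19 (1.52 proximally) and Sp8 (1.44 proximally). Nodal and Activin targets were higher posteriorly in 4 of 14 members, Cer1, Bmp7 (1.67), Eomes (1.44) and Tdgf1 (1.27), and proximally in 1, Eomes (1.59). The medians of the Wnt list (0.37 posteriorly, 0.45 proximally) and of the Nodal list (0.73 and 0.36) lay at percentile 100, as did that of definitive endoderm in both contrasts (0.28 proximally). BMP targets were higher proximally in 5 of 10 members, including Id1, Hand1 (1.96), Id2 (1.73) and Msx1 (1.61), and in 0 posteriorly. That list's median was 1.09 proximally (percentile 100) and 0.16 posteriorly (percentile 99.8). Extraembryonic ectoderm and trophoblast genes were higher proximally in 2 of 7 members, Hand1 and Tfap2c (1.27). In the additive model Gata6 (adjusted p = 0.172) did not pass posteriorly, nor did Gata4 (0.167), Hand1 (0.176), Id2 (0.141) and Tfap2c (0.0582) proximally. Elf5, a factor of the extraembryonic ectoderm that borders the proximal epiblast, stood at 2.59 FPKM in the anterior-proximal library against 0.163, 0.307 and 0.370 in the anterior-distal, posterior-proximal and posterior-distal libraries, and was chosen after its values were seen. Extraembryonic tissue in the anterior-proximal library was not excluded.

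The mesenchymal list held 2 of 13 members higher in each contrast, Snai1 and Cdh11, and its medians were 0.43 posteriorly and 0.38 proximally (percentile 100 in both). In the additive model Cdh11 passed neither posteriorly (1.8, adjusted p = 0.197) nor proximally (2.04, adjusted p = 0.125). Cdh11 was also the 1 of 8 feeder markers that differed. The epithelial list had 0 of 18 members past 2-fold, but its median lay at -0.39 posteriorly and -0.32 proximally, below all random lists (percentile 0), with Cldn4 at -0.84 and -0.81. Tdgf1 was the 1 of 17 core pluripotency members higher posteriorly, while that list's median was -0.076 posteriorly (percentile 4.08) and -0.078 proximally (percentile 1.29). Fst (1.54 posteriorly, 2.11 proximally) was the 1 of 19 of the primed list, whose median was lower, at -0.12 posteriorly (percentile 0.05) and -0.20 proximally (percentile 0). Tfap2c was the 1 of 12 primordial germ cell members higher proximally, and that list's median was -0.17 posteriorly (percentile 0.27). In the naive, FGF and ERK, glycolysis, oxidative phosphorylation, cholesterol, ATF4, p53, DNA methylation, cell cycle, ribosomal and histone lists 0 members differed in either contrast, and the medians of these lists lay between -0.23 and 0.14. Some of these small shifts still lay outside the central 95% of random lists: posteriorly FGF and ERK targets at 0.11 (percentile 99.9), glycolysis at -0.095 (0.20), ribosomal genes at -0.095 (0), naive genes at -0.23 (2) and histones at -0.23 (0.58). Proximally these were glycolysis at 0.14 (100), ATF4 genes at -0.13 (0.02), p53 targets at -0.10 (0.40), ribosomal genes at 0.017 (99.5) and histones at -0.19 (0.96). Neuroectoderm, visceral endoderm and Hox genes had fewer than 5 members kept. The counts of 49 and 51 depend on the pseudocount, at 93 and 105 with 0.1 and 11 and 14 with 5, and they were 30 and 27 with a mean of at least 5 FPKM.

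Which region the culture difference leans to was asked next, over 10435 genes in both mouse tables. The rsEpiSC minus EpiSC change had little relation to any region: across genes, Pearson's r with a region's deviation from the mean of the regions was -0.091 for anterior-proximal, -0.051 for anterior-distal, 0.095 for posterior-proximal and -0.022 for posterior-distal. Spearman's rho was -0.10, -0.056, 0.080 and 0.011 in the same order, so the sign for the posterior-distal region depends on the measure. Genes are not independent replicates, and no p-value is given. The 786 genes lower in rsEpiSC had a median deviation of -0.069 in the posterior-proximal region (percentile 0) and of 0.041 in the anterior-distal region (percentile 100). The 582 genes higher in rsEpiSC had medians between -0.0091 (anterior-proximal, percentile 0.10) and 0.011 (posterior-distal, percentile 99.8).

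In human cells the comparison asked what the IWR1 and FGF2 medium goes with in H1 and H9. The pluripotency factor POU5F1 was abundant in both groups, at 214 ± 13.0 FPKM in ESC and 222 ± 16.7 in rsESC (log2 fold change 0.05, adjusted p = 0.780). DUSP6, a feedback phosphatase of FGF and ERK signalling, fell from 74.3 ± 16.1 to 9.03 ± 0.390 (hg19 chromosome 12, 89741602 to 89746636; log2 fold change -2.89, SE 0.12, adjusted p = 0.00707). The amino acid transporter gene SLC7A5 fell from 101 ± 25.5 to 22.7 ± 0.484 and the Nodal antagonist LEFTY1 from 4.68 ± 2.34 to 0.402 ± 0.145. NPTX1, a neuronal pentraxin, rose from 2.72 ± 2.38 to 65.7 ± 10.7 and TXNIP, an inhibitor of thioredoxin, from 13.8 ± 6.53 to 102 ± 3.64.

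Of 13214 genes, 325 changed, 251 higher and 74 lower in rsESC by limma with the cell line in the model. In a check of the lines, 1 of the 2 rsESC libraries lay nearer the ESC library of the other line label. The count without the line is therefore given too: 292, 229 higher and 63 lower. If that rsESC library is of the other line, the model pairs the libraries wrongly and the rsESC minus ESC values also hold a difference between the lines. Both rsESC libraries would then be of 1 line, so the p-values would rest on 1 rsESC line and may be too small. With genes that differed at least 2-fold between the ESC libraries left out, 312 changed. The 2 groups did not overlap for 67.9% of genes, where chance gives 33.3%. Next to NPTX1 (4.32) and TXNIP (2.87), the largest rises were in MAP1LC3C (2.78), PLA2G2A (2.57), LTB (2.50), PRODH (2.30), TMEM64 (2.30), HLA-DQB1 (2.23), FEZ1 (2.15) and CRABP2 (2.14). After DUSP6 the largest falls were in the receptor gene TEK (-2.70), D21S2088E (-2.16), SLC7A5 (-2.09), LEFTY1 (-1.96), P2RY1 (-1.88), LRAT (-1.87), SPRY4 (-1.75), CCDC152 (-1.72) and LRRC61 (-1.69). SOX2 (0.61, adjusted p = 0.0214) and NANOG (-0.83, adjusted p = 0.0232) differed by less than 2-fold.

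**Figure D4:**
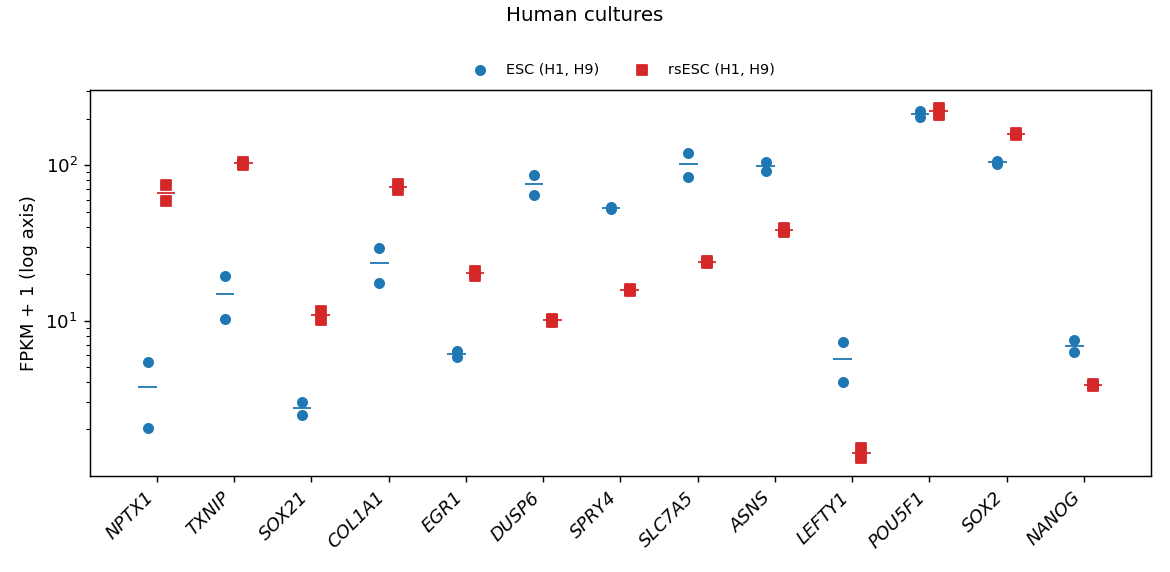
FPKM + 1 (log axis) of named genes in human ESC (circles) and rsESC (squares), H1 and H9 as points and their mean as a line. NPTX1 lies at 2.72 FPKM on average in ESC and 65.7 in rsESC, and DUSP6 at 74.3 and 9.03.

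ATF4 and amino acid stress genes fell, 6 of 21 lower and 0 higher (6 and 0 adjusted over the list alone), among them SLC7A5, CHAC1 (-1.38), ASNS (-1.35) and PSAT1 (-1.29). The list's adjusted p was 7.9e-10, and 0.762 with an estimated correlation. FGF and ERK targets fell as a list with 4 of 18 lower and 1 higher (the same adjusted over the list alone), adjusted p = 2.1e-05 and 0.762 with an estimated correlation. DUSP6, SPRY4 and IL17RD (-1.05) fell, while the immediate early gene EGR1 rose from 5.10 ± 0.428 to 19.1 ± 0.986. Nodal and Activin targets did not pass as a list (adjusted p = 0.0655), with LEFTY1, FGF19 (-1.12) and NODAL (-1.09) the 3 of 12 that fell (3 adjusted over the list alone). That list was called lower without ESC replicate 2 (adjusted p = 0.00687) or rsESC replicate 1 (0.0430), both without the line, and with the genes that differ between the ESC libraries left out (0.04998), in a range up to 0.977 over the alternatives other than the estimated correlation. Genes of the post-implantation epiblast and primed state were lower as a list, with 1 of 18 called, NODAL (1 adjusted over the list alone). Their adjusted p was 0.0219, 0.762 with an estimated correlation, 0.0796 after quantile normalization and 0.245 without ESC replicate 1.

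Extraembryonic ectoderm and trophoblast genes rose as a list, 2 of 5 higher (2 adjusted over the list alone), adjusted p = 0.000692 and 0.762 with an estimated correlation. The members that rose were SOX21 (1.99), also a neural factor, and TFAP2C (1.49). Glycolysis genes rose as a list (3 of 24 higher, 3 adjusted over the list alone, adjusted p = 0.0219, and 0.762 with an estimated correlation), with SLC16A3 (1.91), ENO2 (1.41) and BNIP3 (1.11). Oxidative phosphorylation genes were higher as a list with 0 of 37 called (0 adjusted over the list alone), adjusted p = 0.000575 and 0.762 with an estimated correlation, while 4411 genes of all had an unadjusted p under 0.05 in limma. Its members SDHC, on the long arm of chromosome 1, and NDUFA1 were at 0.73 and 0.52.

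The remaining lists did not pass. Core pluripotency (adjusted p = 0.877) had 1 of 18 higher and 1 lower, L1TD1 (-1.24), naive pluripotency (0.998) 0 of 5 called with NR5A2 at -0.80, and neuroectoderm (0.115) 1 of 7 higher, NES (1.12). Canonical Wnt targets (0.797) had 0 of 12 called with BMP4 at 0.79, and BMP targets (0.759) 2 of 7 higher, ID4 (1.16) and ID1 (1.11). Cholesterol biosynthesis (0.452) had 2 of 25 higher, PMVK (1.13) among them, p53 targets (0.144) 0 of 20 with BTG2 at 0.97, and primordial germ cell genes (0.759) TFAP2C higher of 8. The epithelial list (0.148) had TJP3 (1.40) higher of 20 and the mesenchymal list (0.347) S100A4 (1.46) higher of 15. Feeder markers (0.144) had COL1A1 (1.67) and COL1A2 (1.10) higher and THY1 (-1.16) lower of 16. DNA methylation enzymes (0.0573) had 0 of 12 called with TET1 at -0.64, and cell cycle genes (0.759) 0 of 34 with CDKN1C at 0.86. Ribosomal protein genes (0.334) had RPL39 (1.18) higher of 76 and histones (0.587) HIST1H2BK (-1.0) lower of 12. Each of these counts was the same adjusted over the list alone. Some of these lists passed when 1 library was left out together with the line: neuroectoderm, higher, without ESC replicate 1 (adjusted p = 0.0376, up to 0.266 over the alternatives other than the estimated correlation) or rsESC replicate 1, and the epithelial list, higher, without ESC replicate 1 (0.0290, up to 0.773). DNA methylation enzymes were lower without ESC replicate 2 (0.0419, up to 0.211) or rsESC replicate 1, and also at 0.04998 with the genes that differ between the ESC libraries left out. The p53 targets were higher without rsESC replicate 1 (0.0430, up to 0.779), and ribosomal protein genes with a mean of at least 5 FPKM (0.0375, up to 0.892). Primitive streak (4 kept), definitive endoderm (3), visceral endoderm (4) and Hox genes (0) were not tested.

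Genes of chromosome 1 from 140 Mb (hg19), its long arm, were higher in rsESC in 89.8% of 586 cases, with a median log2 fold change of 0.47. They gave 21.1% of the higher calls, TXNIP, MAP1LC3C, CRABP2, NES, PMVK and S100A4 among them, from 4.43% of the genes. Without them 265 genes changed, and the adjusted p of oxidative phosphorylation was 0.000505 and that of ATF4 genes 9.8e-11. The count rests on how the spread is estimated. With 1 rsESC library left out, and without the cell line, it came from the ESC pair alone (SD of the log2 difference 0.33, against 0.15 in rsESC). Of the main calls tested, 0 of 313 changed sign without rsESC replicate 1 and 0 of 314 without replicate 2. Here too a kept sign was nearly fixed in advance, since the genes were called with all libraries in. The numbers called in such fits are given below with the processing. The count was 0 without a filter on low values (4188 at an unadjusted p under 0.05 in limma), 509 and 76 with pseudocounts of 0.1 and 5, and 183 with a mean of at least 5 FPKM.

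**Figure D5:**
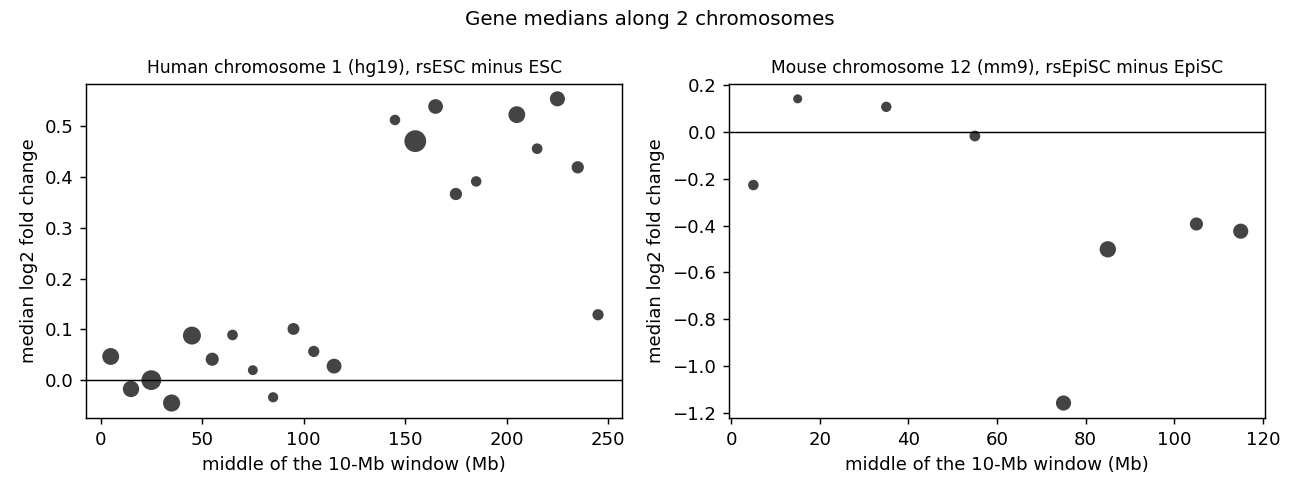
Median log2 fold change of the genes in 10-Mb windows with at least 20 genes along human chromosome 1 and mouse chromosome 12, point size growing with the number of genes. Human windows from 140 Mb lie between 0.13 and 0.55, and the lowest mouse window lies at -1.16.

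Mouse and human changes were set side by side to ask whether both species moved alike. A few genes did: LEFTY1, NODAL and SLC7A5 fell in both, and SOX21, CRABP2, FEZ1, ID1 and PMVK rose in both. More went opposite ways, with TFAP2C, TJP3, COL1A1, SPP1, LGALS1 and BST2 lower in mouse and higher in human. SPP1, LGALS1 and BST2 were chosen after their values were seen. Over 9819 genes shared by symbol, Pearson's r across genes was -0.093 (SD 0.057 over 16 pairings of single libraries) and Spearman's rho was -0.12. Both species called 15 genes higher (9.06 by chance) and 9 lower (3.18 by chance), while 30 were lower in mouse and higher in human (12.4 by chance) and 2 the reverse (2.32 by chance). Of 1386 genes called in mouse, 42.1% had the same sign in human, beside 45.9% of all 9819. Genes lower in mouse had a human median of 0.16 (percentile 100) and genes higher in mouse 0.040 (percentile 25.9). Genes higher in human had a mouse median of -0.23 (percentile 0) and genes lower in human -0.58 (percentile 0). Both sets leaned lower in mouse, so the fall of the lower human genes does not by itself show a shared direction.

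The rhesus and chimpanzee libraries have no conventional counterpart, so their levels were placed between human ESC and rsESC. Genes that fell in human rsESC lay nearer the rsESC level in 63.9% of 72 cases in rhesus (exact 95% interval 51.7 to 74.9) and 70.8% in chimpanzee (58.9 to 81.0). For rhesus this rests on the settings: the share was 56.1% with a pseudocount of 0.1 (46.1 to 65.7), 54.8% with a mean of at least 5 FPKM (38.7 to 70.2) and 54.5% after quantile normalization (44.2 to 64.4), all with 50% inside the interval. In chimpanzee only quantile normalization brought 50% inside it (59.4%, 49.2 to 69.1). Genes that rose in human rsESC lay nearer ESC, with 31.8% of 242 nearer rsESC in rhesus (26 to 38.1) and 33.9% in chimpanzee (27.9 to 40.2). Over both directions, 39.2% of 314 lay nearer rsESC in rhesus (33.7 to 44.8) and 42.4% in chimpanzee (36.8 to 48.0). In each direction most genes thus lay nearer the lower human level, which reads missing on human transcripts would also give. The intervals cover counting error over genes only. NPTX1 was at 0.474 FPKM in rhesus and 1.35 in chimpanzee, below the human ESC mean of 2.72. DUSP6 was at 210 and 73.9 FPKM, LEFTY1 at 177 and 0.369, POU5F1 at 125 and 239, and TXNIP at 30.4 and 81.2. Across 13338 genes, Pearson's r with the human libraries was 0.79 to 0.80 for rhesus and 0.90 to 0.91 for chimpanzee. Species, line, culture and mapping to human transcripts cannot be told apart in these libraries.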

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

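All tests in this part were chosen only after the result was seen, except 3 on mouse chromosome 12: the share of lower genes on the whole chromosome, the median of its uncalled genes and the comparison with the epiblast.

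Of 110 named genes compared between the species, 5 moved in opposite directions in mouse rsEpiSC against EpiSC and in human rsESC against ESC. Their mean change was at least 2-fold in each species, and the libraries of the groups compared did not overlap. The mouse and human log2 fold changes were -3.87 and 1.67 for Col1a1, -1.35 and 2.50 for Ltb, -1.5 and 1.46 for S100a4, -1.85 and 1.49 for Tfap2c, and -2.09 and 1.40 for Tjp3. All 5 were called in human, while Ltb (adjusted p = 0.278) and S100a4 (adjusted p = 0.0935) did not pass in mouse. For each of these genes the difference between species was not tested.

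The first pattern is that the libraries labelled rsEpiSC lacked Pou5f1 and epithelial transcripts and carried neuroectoderm transcripts. Pou5f1 cannot decide whether the labels of the mouse groups were exchanged, since both cell types are pluripotent by name. The rsEpiSC libraries kept 1.23% of the EpiSC level of 888 FPKM. Readouts of the media went both ways. Wnt targets ran against the label of an IWR1 culture (5 of 14 higher in rsEpiSC, 0 lower, Axin2 from 3.88 to 14.3 FPKM). Nodal and Activin targets ran with the label of activin A in the EpiSC medium (9 of 12 lower in rsEpiSC, 0 higher). Neither list reads the medium alone, so neither decides on the labels. Tdgf1 is also a member of the core pluripotency list, and the signal Wnt1 itself rose to 50.4 FPKM in rsEpiSC. A minor share of other cells in a pluripotent culture is argued against by epithelial members, which kept a median of 0.937% (at most 18.4%). Feeder cells as its source are argued against by 3 collagens, whose sum was 17.5 and 21.3 FPKM in the rsEpiSC libraries and 28.3 and 114 in EpiSC (27.3% of the means, 68.5% without EpiSC replicate 2), but this rests on Col1a1 (1.13 and 1.82 against 19.4 and 61.5), since Col1a2 (16.2 and 16.8) exceeded EpiSC replicate 1 (8.09) and 7 of 14 feeder markers lay higher, Fbln2 (1.86) as a call, so a small share of feeders stays open. If the factor that the rsEpiSC label leaves out is FGF2, a response to FGF2 and IWR1 shared with human cells is argued against by the human neuroectoderm list, with 1 member called higher of 7 and RAX, EN1 and PAX6 at most at 0.095 FPKM in human rsESC. An exchange of labels stays open, and libraries of other, neural-like cells may have come under this label or column name. The culture, with several medium components changed at once, may also have changed the cells. Statements on rsEpiSC as a pluripotent state may therefore not rest on these libraries alone. In the check for mixed-up samples, 1 of the 4 mouse culture libraries did not match the other 3. That check does not test cell type, and 1 library cannot account for a loss of Pou5f1 seen in both rsEpiSC libraries (8.58 and 13.2 FPKM).

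The second pattern is that genes of human chromosome 1 from 140 Mb were higher in both rsESC libraries. Their share was 89.8% and their median log2 fold change was 0.47, where 3 copies in place of 2 would give 0.58, so extra copies of the long arm may be the source. A response of single genes is argued against by the uncalled genes there, with a median of 0.44, and library scaling or depth by the highest median of another chromosome, 0.12. A check used 23 autosomal genes that differed at least 4-fold between the ESC libraries. Both rsESC libraries lay nearer the same ESC library for 21 of them. This placed 1 of the 2 rsESC libraries nearer the ESC library of the other line label. A difference between the lines may therefore be part of the group difference, and the shift may have been seen in 1 line only. The check cannot tell a wrong label from another difference between the ESC libraries. No DNA was measured, and an effect of the culture on a whole arm was not tested.

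The third pattern is that genes of mouse chromosome 12 were lower in rsEpiSC. A response of single genes is argued against by the uncalled genes there, with a median of -0.23, and library scaling or depth by the lowest median of another chromosome, -0.016. Against the epiblast, chromosome 12 stood 0.40 above other genes in EpiSC (0.37 and 0.44 in its libraries) and 0.020 in rsEpiSC, so a gain in the EpiSC cultures may be the source rather than a loss in rsEpiSC. A copy difference itself stays open, because 68.4% of genes on the whole chromosome and 79.0% from 70 Mb were lower, both short of the 80% set as its bound. Below 70 Mb the median was 0.0048, and no DNA was measured.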

How the results depend on the processing

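The alternatives that leave out chromosome regions, keep chromosome Y genes and X-inactivation RNAs, leave out genes that differ between the ESC libraries, drop the line in the cross-species comparisons or fit the epiblast additively were chosen only after the result was seen. Of all results under alternatives, 1290 for mouse named genes and 828 for human named genes kept their direction and their side of the threshold. Another 162 and 168 fell short of the threshold, 7 and 21 came to pass it, and 1 and 3 changed sign. Named genes that passed were lost most often without a filter on low values (64 of 91 in mouse, 46 of 46 in human), then without rsEpiSC replicate 1 (37 of 91) or 2 (34 of 91), and in human as often without either rsESC replicate (46 of 46).

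The number of changed mouse genes (1819) was 952 with a pseudocount of 5, 341 without a filter on low values and 1149 with a mean of at least 5 FPKM. It ranged from 394 without rsEpiSC replicate 1 (432 without replicate 2) to 3128 without EpiSC replicate 2. The number of changed human genes (325) was 509 and 76 with pseudocounts of 0.1 and 5, 183 with a mean of at least 5 FPKM and 1714 with no minimum fold change. Without a filter limma called 0 (4188 at an unadjusted p under 0.05). Leaving out 1 library together with the cell line gave 0 without rsESC replicate 1 (2066 unadjusted) or 2 (1929 unadjusted) and up to 566 without ESC replicate 2. A group left with 1 library is assumed to vary like the other group.

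With an estimated correlation camera called 0 lists in mouse (10 with the preset one) and 0 in human (6), where 3 mouse and 0 human lists had an unadjusted p under 0.05. That setting has only the residual degrees of freedom of the fit (2 in mouse, 1 in human). The human ATF4 list had an estimated correlation of 0.0095, near the preset 0.01, but its unadjusted camera p went from 3.6e-11 to 0.095. These failures therefore do not tell whether correlation among members undoes a list. Called human lists numbered 6 to 10 when 1 library was left out, with 10 without rsESC replicate 1. By fry, the mouse cholesterol, ATF4, p53 and cell cycle lists did not pass (adjusted p = 0.0675, 0.169, 0.0675 and 0.187). The other mouse lists called by camera passed, the highest at 0.0479 (oxidative phosphorylation), as did DNA methylation enzymes (0.0267), which camera did not call. In human no list passed by fry, with the lowest adjusted p at 0.0665 (canonical Wnt targets). POU5F1 in human, at 0.052, was -0.0082 after quantile normalization and -0.025 to 0.13 when 1 library was left out (-0.010 without ESC replicate 2). Hist3h2ba was -0.058 without EpiSC replicate 2 and 1.73 without EpiSC replicate 1.

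Genes that differed between posterior and anterior epiblast numbered 93, 11 and 30 (49), and between proximal and distal 105, 14 and 27 (51), with a pseudocount of 0.1, of 5 and a mean of at least 5 FPKM, and an additive model called 32 and 34. Correlations of the culture change with the regions, with a pseudocount of 5, were -0.079 (anterior-proximal), -0.042 (anterior-distal) and 0.079 (posterior-proximal). Spearman's rho was -0.10, -0.056 and 0.080, and 0.011 for posterior-distal, where Pearson's r was -0.022 and, with a mean of at least 5 FPKM, -0.035. After quantile normalization the anterior-distal value was -0.059 and the posterior-proximal value 0.0998. With 1 library left out they ranged from -0.095 to -0.070, from -0.052 to -0.045 and from 0.083 to 0.096. The mouse-human correlation moved by less than its spread, while the rhesus share of lower genes (63.9%) fell to 54.5% after quantile normalization, with 50% then inside its interval; the cell line cannot move that correlation in this balanced design. The cause was not tested for any of these differences, apart from fewer or more genes or libraries entering a fit. Low depth limits the rhesus library most, where 1 read per kilobase equals 0.102 FPKM.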

Other observations

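The values in this part were looked up, and the genes chosen, only after the result was seen. The maternally expressed imprinted RNA Meg3, a neighbour of Rian on chromosome 12, rose from 0.428 ± 0.552 to 18.3 ± 10.3 FPKM in mouse rsEpiSC (mean ± SD, n = 2, limma adjusted p = 0.0166), and Mirg from the same cluster rose from 0.212 ± 0.299 to 5.28 ± 1.32 (adjusted p = 0.0145). H19 and Cdkn1c, both on chromosome 7, differed between the rsEpiSC libraries, with H19 at 70.2 and 6.76 FPKM in replicates 1 and 2 and Cdkn1c at 32.8 and 5.77, against at most 0.724 in EpiSC. The lysosomal enzyme gene Hexa was at 262 and 113 FPKM in the EpiSC libraries and at 0.058 and 28.9 in rsEpiSC replicates 1 and 2. None of H19, Cdkn1c and Hexa passed the test (adjusted p = 0.0558, 0.0528 and 0.107).

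Levels in the cultures correlated across 11768 genes with those in the regions at 0.71 for EpiSC replicate 1, 0.80 for EpiSC replicate 2 and 0.80 to 0.81 for the rsEpiSC libraries. The EpiSC libraries differed more from each other here than EpiSC replicate 2 from rsEpiSC. These values therefore do not show which culture is nearer the epiblast. Single genes went both ways. Pou5f1 was at 586 to 647 FPKM in the regions, 788 and 987 in EpiSC and 8.58 and 13.2 in rsEpiSC. Otx2 was at 133 to 193 in the regions, 22.4 and 22.1 in EpiSC and 95.6 and 68.8 in rsEpiSC.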
